A study of Mus musculus with 5 samples.

How the data were processed

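Total RNA of mouse lung ILC2s was extracted with Trizol, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. There were 3 arrays of wild-type and 2 of IL-33 knockout cells, each a biological replicate per the labels. The deposited values are log2 probe-set signals, and the tools named are Affymetrix Expression Console and RMA, per the submitters' processing notes. Their versions, the RMA settings and the level of summary were not given in the sources used here. RMA as commonly run subtracts background, equalises the distribution over arrays and summarises probes, so a shift of all transcripts together cannot be seen in such values. Many deposited values were exactly equal between arrays: 498 of the genes tested had 1 value on all 5 arrays and 36.36% had 5 distinct values, which makes the spread of some genes 0 or too small.

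Of 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 had none and stayed unnamed. Symbols were checked through gene identifiers against the RefSeq table of assembly GRCm38.p6, in which 23328 of the probe sets with 1 symbol were found. The files name no genome build. That table was used for names, gene order and distances from Il33. Per gene the probe set with the highest mean was used, for 22180 genes, and the 25% of genes with the lowest mean were left out, so that 16635 were tested. Each of the 5 columns was assigned to its sample and group by the labels.

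Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05), without a block. The 33 gene lists were fixed before the data were examined. Those with at least 5 members tested, 31 lists, were tested with camera at a preset inter-gene correlation of 0.01, with the correlation estimated from the data and fry as alternatives. Members of a list were also adjusted over the list alone. For single values, a two-sided exact permutation over the 10 splits of 5 arrays cannot go below p = 0.1, so none is printed. Genes near Il33 were compared with the others by Fisher's exact test, with a window of 10 Mb. The rule for named genes, also fixed beforehand, took Il33 and a further gene that is not reported here. It then took up to 12 genes in each direction, filled by the largest log2 differences among genes with an unadjusted p below 0.05, no overlap of the groups and a mean above the median gene, and up to 4 members with the smallest p from each list. Predicted genes, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments were left out. Bpifa1, Scgb1a1, Ranbp6, Uhrf2, Zfand5, Fam122a, Mlana, Rpl31-ps20, Ermp1, Jun, Junb, Gzma, Cbr2, Olfr782, Usp9y, Zfy2, Kdm6a, Kdm5c and Ddx3x were named after their values were seen. Calcrl, Pecam1 and Olfr635 were also named afterwards and were not followed over the alternatives.

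The fit was tested on simulated arrays of 3 and 2 for 16635 genes, each with its own spread, with 200 genes changed. It recovered 38% of genes changed 2-fold, 66% of those changed 4-fold, 74% of those changed 8-fold and 84% of those changed 16-fold. It called 14 of 16435 unchanged genes, a larger share of all calls than of the unchanged genes. With 1 spread for every gene instead, it recovered 38% of genes changed 2-fold and 100% from 4-fold up, and called 4 unchanged genes. With each gene's own spread, 5.96% of the unchanged genes had an unadjusted p below 0.05. With no gene changed, 5.86% of 16635 genes had such a p, somewhat more than a uniform p gives. For the fits with 1 knockout array, unchanged knockout arrays were drawn 20 times around the wild-type mean of each gene, with that mean's error and the gene's spread between the knockout arrays, after seeing the data. Alternatives covered the filter on dim genes, the probe sets per gene, quantile normalization and median centring, the variance model, array weights, the replicate number as a block, leaving out each array, thresholds, a minimum fold of 1.2, and windows of 5 and 20 Mb. Restricting the test to genes with at least 4 distinct values, counts at an unadjusted p below 0.05, and neighbours counted at an unadjusted p below 0.01 were added after seeing the data.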

Results

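Gene expression was measured in group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes that respond to alarmins such as IL-33, taken from the lungs of naive male mice according to the labels. The 5 arrays held 3 biological replicates of wild-type cells and 2 of cells from IL-33 knockout mice, and each reported 41345 probe sets as log2 signals. Medians lay between 4.29 and 4.33 log2 units on all 5 arrays. The number of arrays limits the precision of every value. Pearson's r across probe sets, which are not independent replicates, was 0.929 to 0.933 between wild-type arrays, 0.893 between the knockout arrays and 0.894 to 0.918 between genotypes. The design asks which transcripts differ in lung ILC2s of mice that lack IL-33.

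Il33 itself, an alarmin made mainly by epithelial and stromal cells, gave a signal near the floor in both genotypes. Its probe set read 3.36 ± 0.04 (SD, n = 3) in wild-type arrays and 3.87 ± 0.11 (SD, n = 2) in knockout arrays, against 4.48 for the median gene. Being among the 25% of genes left out as dim, it was not tested. The part of the gene removed by the knockout and the position of the probes were not given in the sources used here, so this probe set does not check the genotype labels.

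ILC2 identity transcripts had a median difference of -0.02, knockout minus wild type on the log2 scale, with a few standing apart. Icos, a costimulatory receptor, was at 8.41 ± 0.19 (SD, n = 2) in knockout arrays and 7.14 ± 0.12 (SD, n = 3) in wild-type arrays, a 2.41-fold difference, and both knockout arrays lay above all 3 wild-type arrays. The gene for the IL-25 receptor subunit, Il17rb, differed by -0.23 and that for the neuromedin U receptor, Nmur1, by -0.56 on the log2 scale, both lower in each knockout array than in every wild-type array. The transcription factor gene Gfi1 differed by 0.49, upward. Of the 27 list members tested, 13 were above and 14 below 0 in difference, none passed over all genes tested, and 1, Icos, passed when adjusted over the list alone. With limma, the adjusted p of Icos over all genes was 0.402, and the list's camera adjusted p was 0.794.

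Among type 2 cytokines and effector products, the transcript standing farthest apart was Tnf, which encodes an inflammatory cytokine. Its signal was 8.26 ± 0.39 (SD, n = 3) in wild-type and 6.09 ± 1.01 (SD, n = 2) in knockout arrays, a difference of -2.18 with a standard error of 0.53. Il4 was 0.79 higher, and Ltb and Dgat2, a triglyceride synthesis gene, differed by -0.39 and -0.77. Over the alternatives the difference of Il4 ranged from 0.40 to 1.19 and that of Dgat2 from -1.14 to -0.40. None of the 28 members tested passed, limma's adjusted p for Tnf was 0.514, and the list's camera adjusted p was 0.586.

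Genes of costimulation and of receptors showed differences in both directions. Tnfsf10, which encodes the death ligand TRAIL, differed by -1.76 (SE 0.33), while Nt5e and Cd28 were 0.53 and 0.78 higher. Both chains of the interferon-gamma receptor had higher signals in knockout arrays, by 0.71 for Ifngr1 and 0.99 for Ifngr2, and Il9r differed by -0.43. Among receptors for neuropeptides, lipids and hormones, Ltb4r1, a leukotriene B4 receptor gene, differed by -1.08, Ramp3 by 0.33 and the serotonin receptor gene Htr1b by 0.87. The difference of Ltb4r1 ranged from -1.50 to -0.66 over the alternatives and that of Ramp3 from 0.20 to 0.47. Adhesion and trafficking genes included Itgb2 at -0.55 and Selplg at -0.52, with Rgs1 at 0.54 and Rgs2 at 0.35. The difference of Rgs2 had the opposite sign, -0.04, when its probe sets were averaged. Of these lists, 24, 27, 23 and 30 members were tested and none passed over all genes; adjusted over the list alone, 1 costimulation gene, Icos again, passed. Their camera adjusted p values were 0.586 for costimulation, 0.973 for cytokine receptors, 0.139 for neuropeptide and hormone receptors and 0.685 for trafficking.

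Feedback targets of IL-33, NF-kB and MAPK signalling had the lowest p of the 31 lists tested, and that p did not reach the threshold. Of 34 members, 25 were lower and 9 higher in knockout, with a median difference of -0.19. Pim1, a kinase gene, and Gadd45b, a stress response gene, differed by -0.41 and -0.43, while the MAPK phosphatase genes Dusp10, at 1.57, and Dusp5, at 0.75, were among the higher ones. The camera test gave an adjusted p of 0.0598 downward with the preset correlation and adjusted p = 0.927 with an estimated correlation. The list mean was not lower in both knockout arrays: it was 7.34 in knockout replicate 1 and 6.96 in replicate 2, against 7.19 to 7.34 in wild type. Without wild type replicate 2 the list's camera adjusted p was 0.0401, with no filter on dim genes it was 0.0291, and the highest over the alternatives was 0.963. The list also passed without knockout replicate 1, where replicate 2 is the only knockout array. That array had a high signal of the sex check gene Xist as well, 7.91 against 2.35 to 3.10 on the others. A possible difference of sex cannot be told apart from the genotype there.

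Immediate early genes, which also respond to tissue dissociation, went both ways, with 19 of 29 members above and 10 below 0 in difference. The list mean was 8.69 in knockout replicate 1, against 8.22 in replicate 2 and 8.22 to 8.30 in wild type. Fosl2, an AP-1 factor gene, was 0.92 higher and the heat shock genes Hspb1 and Hsp90aa1 were 0.59 and 0.25 higher. Ccn1 was 0.81 higher. The AP-1 genes Jun and Junb differed by -0.78 and -0.42, both lower in each knockout array than in every wild-type array. No member passed and the camera adjusted p was 0.586. With an estimated correlation the list had an adjusted p = 0.927. Without knockout replicate 2 the camera adjusted p was 0.0465, in a range of 0.0465 to 0.927 over the alternatives.

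Stress, respiratory chain and ribosomal genes included some with higher and some with lower signals in both knockout arrays. Without overlap of the groups, 4 stress genes were higher and 1 lower, and 7 respiratory chain genes higher and 5 lower. Of the ribosomal genes, 7 were higher and 2 lower. Chance gives at most 20% of genes without overlap, less where arrays hold equal values, and the share over all genes tested was 17.96%. Atf4, a transcription factor of the integrated stress response, was at 10.05 ± 0.05 (SD, n = 2) against 9.56 ± 0.07 (SD, n = 3), and Dnajb9, a chaperone gene, was 0.91 higher, while Creld2 differed by -0.55. Ndufb3, a subunit of complex I, was at 7.89 ± 0.08 against 6.69 ± 0.19 and Cox5b, of complex IV, was 0.65 higher. Rps24, Rps18 and Rps20 were 1.02, 0.93 and 0.43 higher, although ribosomal protein genes have many pseudogenes whose transcripts the probes may share. Adjusted over the list alone, Atf4 passed among 23 endoplasmic reticulum stress genes and Ndufb3 among 30 respiratory chain genes. Both had an adjusted p of 0.402 with limma over all genes, and none of the 28 ribosomal genes passed either way. The camera adjusted p was 0.711, 0.794 and 0.280 for the 3 lists.

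In metabolism, 15 of 22 amino acid and polyamine genes and 9 of 22 glycolytic genes were above 0 in difference. The amino acid list mean was 6.65 in knockout replicate 1 and 6.38 in replicate 2, against 6.33 to 6.37 in wild type. Phgdh, of serine synthesis, was 0.76 and Mthfd2 0.31 higher. Pgk1 and Tpi1, of glycolysis, differed by -0.24 and -0.62, Fabp5, a lipid carrier gene, by 0.97, and Fdft1 and Cyp51, of cholesterol synthesis, by 0.79 and 0.50. None of the 22, 22, 23 and 19 members tested of the amino acid, glycolysis, lipid and cholesterol lists passed, and their camera adjusted p values were 0.683, 0.502, 0.683 and 0.919.

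Cell cycle, interferon, survival, progenitor and regulatory lists held few genes that stood apart. Plk1 was 0.16 higher, Ifi35 differed by -0.69, Isg15 by 0.61 and Cdkn1a by 0.43. Sox4, a progenitor factor gene, was at 4.51 ± 0.02 (SD, n = 2) against 4.03 ± 0.05 (SD, n = 3) and was the 1 progenitor gene of 22 that passed adjusted over the list alone; limma's adjusted p over all genes was 0.402. Foxp3 was 0.61 higher at a low signal of 4.26 ± 0.14. No other member of these lists passed. The camera adjusted p was 0.784 for cell cycle, 0.711 for interferon, 0.755 for survival, 0.977 for progenitor and 0.919 for regulatory genes.

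Some transcripts of lung epithelium and endothelium had higher signals in both knockout arrays, and no single gene of them passed the test. Among lung epithelium markers, Epcam was at 4.51 and 4.99 in the knockout arrays and 3.88 to 4.13 in wild type, and the surfactant gene Sftpc was 0.94 higher. Of 19 members tested, 16 were higher. The fry test, which asks whether members move 1 way on balance, gave an adjusted p of 0.0232, while camera gave 0.139 and, with an estimated correlation, adjusted p = 0.927. Among endothelial genes, Cldn5 and Cdh5, both of cell junctions, were 1.59 and 1.44 higher and Epas1 was 0.79 higher, while Kdr differed by -0.15. Calcrl, also on the endothelial list, differed by -0.92 and was lower in both knockout arrays, and Pecam1 differed by 0.09 with overlap of the groups. Of 18 endothelial members, 13 were higher and 5 lower, and the camera adjusted p was 0.486. In knockout replicate 1 the airway secretory transcripts Bpifa1 and Scgb1a1 reached 8.52 and 8.81, against 2.85 to 3.22 and 3.62 to 5.01 in wild type. Bpifa1 read 3.22 in knockout replicate 2, within the wild-type range, and Scgb1a1 5.93. The list means of both types were higher in each knockout array than in every wild-type array, at 4.84 and 4.48 against 4.26 to 4.30 for epithelium and 5.09 and 5.17 against 4.81 to 4.95 for endothelium. This was not particular to them. B cell markers lay at 4.35 and 4.43 against 4.24 to 4.30 and fibroblast markers at 4.45 and 4.46 against 4.30 to 4.39. It also held for the costimulation, amino acid, respiratory chain, ribosomal and neighbour lists.

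No marker of the remaining cell types passed. Median differences were -0.003 for T cell genes, 0.05 for NK cell and ILC1 genes, -0.07 for ILC3 genes, 0.10 for B cell genes, 0.07 for macrophage and dendritic cell genes, -0.02 for mast cell and eosinophil genes, 0.06 for neutrophil genes and 0.06 for fibroblast genes. Their camera adjusted p values ran from 0.428 to 0.919. Erythrocyte and platelet transcripts, with 4 members tested, were too few for the list test and had a median of -0.07. Over all genes tested the median difference was 0.0385, and it was 0.0106 after quantile normalization and -0.0141 after median centring. The list medians, the counts of members above 0 and fry do not take that offset out. Camera compares a list with all other genes. Its direction was downward for the trafficking, interferon, progenitor, regulatory and neighbour lists although their median and mean differences lay above 0. For the ILC2 identity and T cell lists the mean lay above 0 while the median and the test pointed downward.

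Over single genes, the transcripts with the widest differences included tubulins. The signal of Tuba1b, an alpha-tubulin, was 10.39 ± 0.36 (SD, n = 3) in wild type and 6.53 ± 0.60 (SD, n = 2) in knockout, a difference of -3.87 (SE 0.37). That of Tuba1c differed by -2.10 (SE 0.09) at one probe set and by -0.04 at its other, so the alpha-tubulin genes, near-identical copies of each other, are uncertain. Trpd52l3 was 9.92-fold higher (log2 difference 3.31, SE 0.61), Plaur, the urokinase receptor gene, 3.47-fold, and Cstb, a cathepsin inhibitor gene, 2.75-fold, at 8.62 in both knockout arrays. Manea, Nanp, Coq10b, Rnase6, Defa21 and Oser1 were 1.41 to 1.63 higher, besides Dusp10, Cldn5 and Cdh5. Lower in both knockout arrays were Zfp640 (-4.30), Ap5m1 (-2.08), Klrb1-ps1 (-1.90), Slfn2 (-1.85) and Sit1 (-1.75), besides Tnf and Tnfsf10. Zfp640, at 1.79 and 2.20, and Klrb1-ps1, at 3.22 in replicate 1, lay below the lower quartile of all probe sets (3.24 to 3.27) in knockout arrays, so the size of their differences is uncertain. Astx5, Srsy and Btbd35f1, of multi-copy families, differed by -3.0, -2.74 and -2.73 and are uncertain, and further probe sets of Zfp640, Nanp and Oser1 showed smaller differences. None of these 24 genes passed: limma's adjusted p ran from 0.327 to 0.605.

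**Figure D1:**
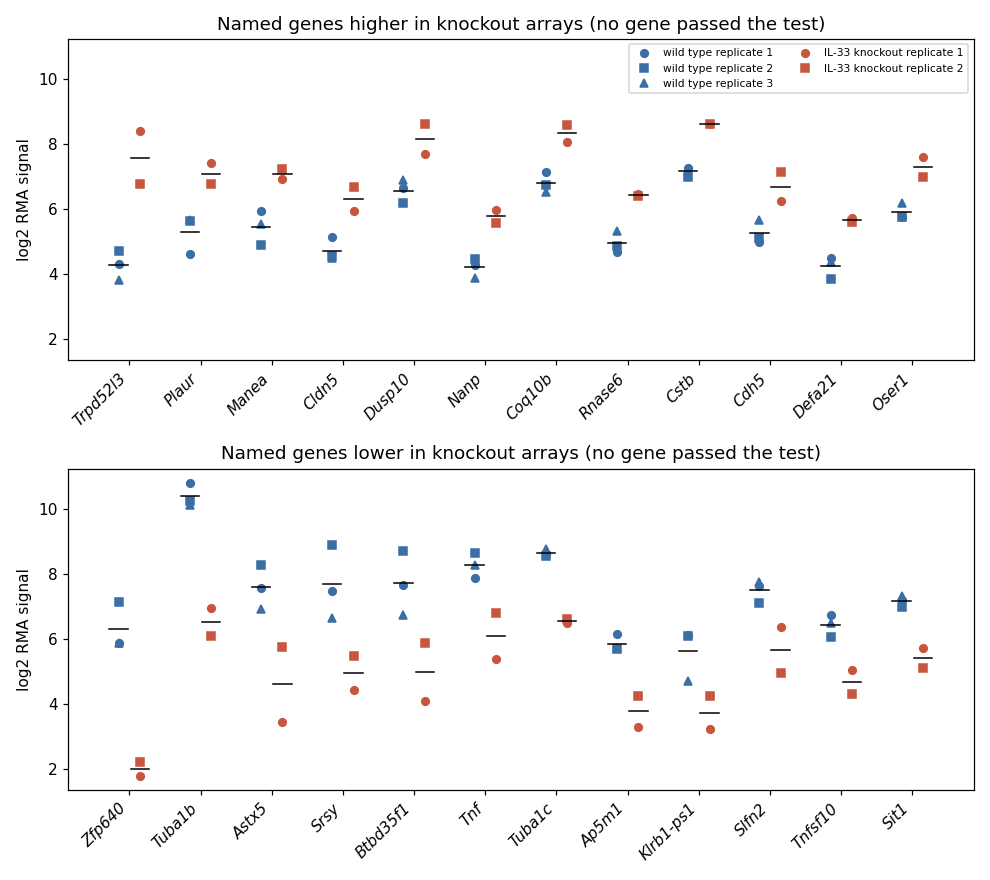
Log2 RMA signal (y axis) of each named gene (x axis) on the 3 wild-type arrays (blue) and the 2 IL-33 knockout arrays (red), 1 symbol per array and a black line at each group mean. The knockout arrays lie apart from the wild-type arrays for every gene shown, which the rule for naming required, and Tuba1b lies at 6.10 and 6.95 in knockout against 10.13 to 10.80 in wild type.

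With limma, 0 of 16635 genes passed an adjusted p of 0.05, and the lowest adjusted p was 0.327. At an unadjusted p below 0.05 there were 1271 genes, 840 higher and 431 lower, where a uniform p gives 832. Below 0.01 there were 355, where a uniform p gives 166. By size the balance was the other way, with 131 genes at least 1 log2 unit higher and 235 at least 1 lower. Of those 235, 79 were olfactory and vomeronasal receptor genes, which made up 2.7% of the genes tested. Wild-type arrays are the majority in the filter on the mean, which can favour dim genes higher in wild type. The counts also do not take out the median difference of 0.0385 over all genes, so neither balance is read as an effect of the genotype. The groups did not overlap for 2988 genes, 17.96% of those tested. For 3 arrays against 2, chance gives 20% for genes with 5 distinct values and at most that for genes with equal values. Since 36.36% of the genes tested had 5 distinct values, the chance share over all genes lies below 20% and was not determined. Single knockout arrays decided the count: 1072 genes passed without knockout replicate 1 and 389 without knockout replicate 2. Of 162 genes called in both fits, which share the wild-type arrays, 33 had the same direction (20.4%). In 20 simulations of knockout arrays without any change, fits with a single knockout array also called genes, so such calls can arise without a genotype effect. Of the simulated genes called in both fits, 43.9% to 55.8% had the same direction. That share follows mainly from drawing the 2 arrays independently around 1 centre. The observed 20.4% lay below that range, but the comparison cannot decide which calls arise without a genotype effect. Most genes called in both fits had opposite directions in the 2 knockout arrays, which a genotype effect alike in both arrays would not give. For the other calls, the part that arises without a genotype effect was not determined. Of the genes named by the rule, Cdc20, Col1a2, Icos, Il4, Itgb7, Kdm5d, Ltb4r1, Rps24, Sit1, Tuba1b, Tuba1c and Xist passed in the former fit and Ngp, Ramp3 and Tuba1c in the latter, as did Bpifa1, which was named afterwards. For the knockout group a lone array was there assumed to vary like the wild-type arrays. In the fit without knockout replicate 1, that lone array is the one with the high signal of the sex check gene Xist. A possible difference of sex cannot be told apart from the genotype in that fit.

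**Figure D2:**
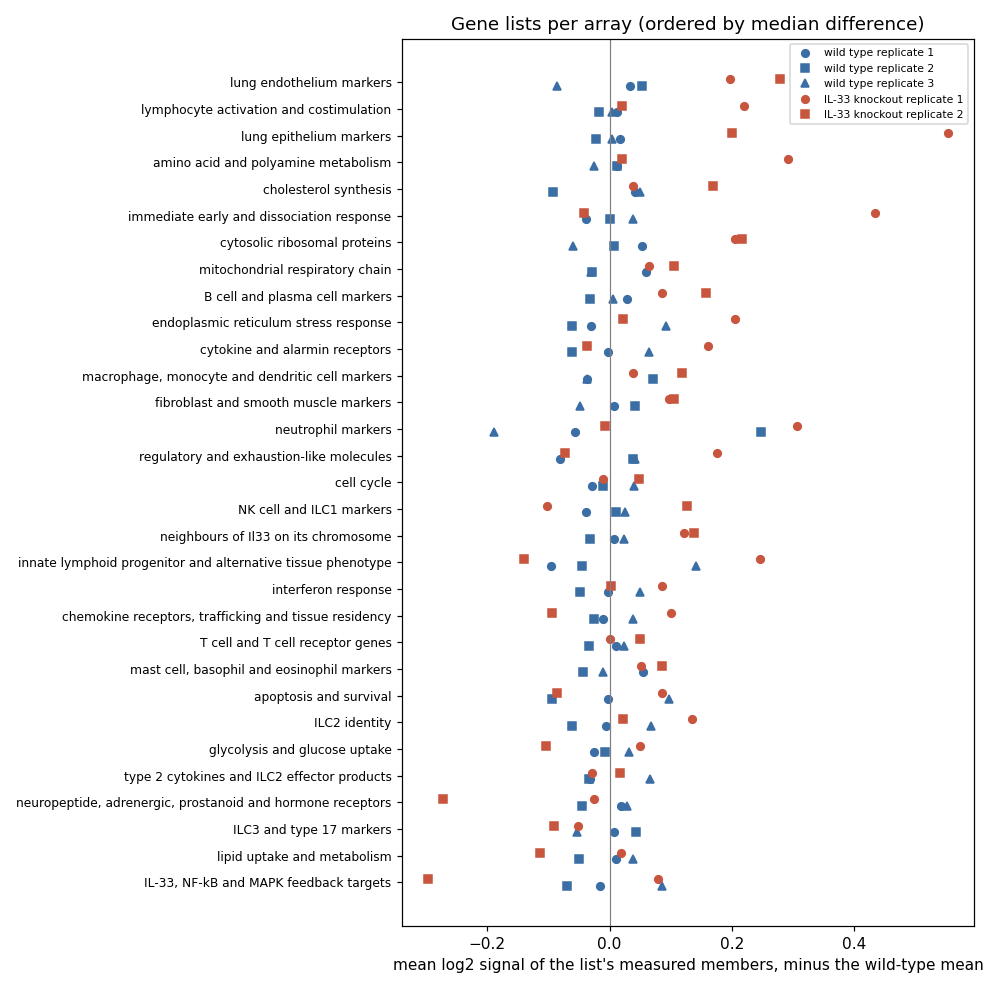
Mean log2 signal of each gene list (rows, ordered by median difference) on each array, minus the mean of the 3 wild-type arrays (x axis, log2 units), with wild type in blue and IL-33 knockout in red. Lung epithelium markers lie highest in knockout replicate 1, at a list mean of 4.84 against 4.26 to 4.30 in wild type, and the IL-33, NF-kB and MAPK feedback list lies at 7.34 and 6.96 in the knockout arrays against 7.19 to 7.34.

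Around Il33, the adjacent gene had the widest difference of the 8 measured genes on each side, and none of those tested passed. In the gene order of the mouse assembly GRCm38.p6, Trpd52l3 is the measured gene next to Il33, and its signal was 8.40 and 6.78 in the knockout arrays against 3.82 to 4.71 in wild type. Ranbp6, on the other side of Il33, differed by 0.31, and Uhrf2, beyond Trpd52l3, by -0.09. Without overlap of the groups, Mlana and Rpl31-ps20 were also 0.39 and 0.33 higher and Ermp1 differed by -0.34. Over the alternatives these differences ranged from 0.20 to 0.58, from 0.10 to 0.46 and from -0.55 to -0.13. Mlana, at 3.76 in wild type and 4.15 in knockout, lay below the median gene (4.48). Rpl31-ps20 is named as a ribosomal pseudogene and read 11.63 in wild type, so its probes may share transcripts of other genes. Over all genes tested the share without overlap was 17.96%. None of 99 genes tested within 10 Mb passed the adjusted threshold. At an unadjusted p below 0.01 there were 3 of 99, Trpd52l3, Zfand5 and Fam122a, an odds ratio of 1.44 (95% interval 0.29 to 4.36) by a two-sided Fisher's exact test with p = 0.472. The list of neighbours fixed beforehand had a camera adjusted p of 0.919.

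**Figure D3:**
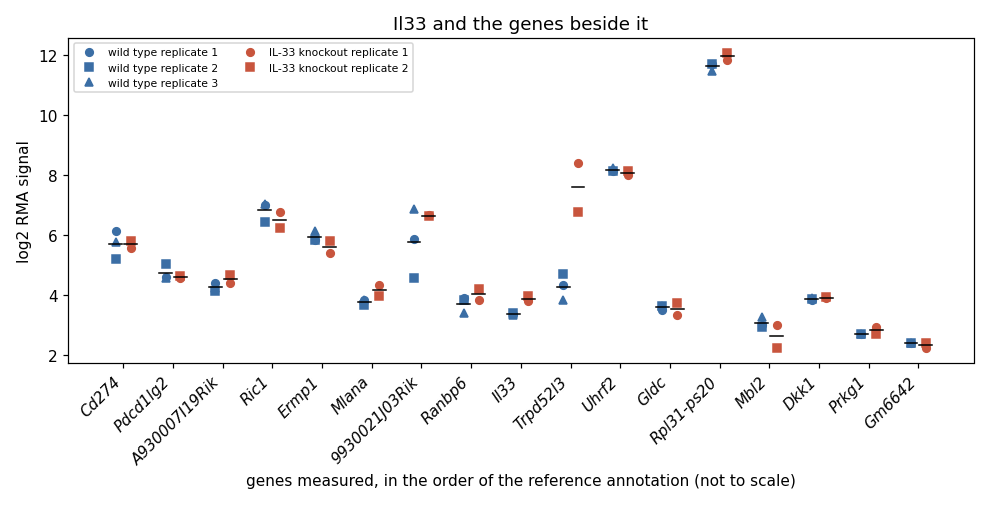
Log2 RMA signal (y axis) of Il33 and the 8 measured genes on each side of it in reference order (x axis, not to scale), with wild-type arrays in blue, IL-33 knockout arrays in red and black lines at group means. Trpd52l3 lies at 8.40 and 6.78 in the knockout arrays against 3.82 to 4.71 in wild type.

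The sex check genes set 1 array apart. Xist, the transcript that silences an X chromosome in female cells, read 7.91 in knockout replicate 2 and 2.35 to 3.10 in the other 4 arrays, all labelled male. Of the Y-linked genes, Eif2s3y read 6.14 in that array against 6.83 to 7.62 in the others and Kdm5d 4.79 against 5.57 to 5.63, while Uty read 7.17 against 5.83 to 6.96. With 4 members this list was not tested.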

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

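The count of 0 genes past limma's adjusted p of 0.05 held in total and in each direction under every filter, probe-set rule, normalization, variance model and array weighting tried, with a minimum fold, at an adjusted p below 0.1, and in the restriction to genes with at least 4 distinct values, an alternative chosen after seeing the data. At an unadjusted p below 0.01 there were 355 genes, 238 higher and 117 lower, and at an unadjusted p below 0.05, also chosen afterwards, 1271, 840 higher and 431 lower, by construction of the looser thresholds. Leaving out 1 array gave 0 to 1072 genes in total, 0 to 588 higher and 0 to 484 lower, with no call when a wild-type array was left out. Without knockout replicate 1 there were 1072 and without knockout replicate 2 there were 389. Exactly equal wild-type values took part in this: 45.6% and 57.6% of those calls had 3 equal wild-type values, against 10.7% of all genes tested. The number of gene lists called was 0 in the main test and 1 with no filter on dim genes, 1 with fry, and 0 to 1 when 1 array was left out; the cause was not tested. The list called was the IL-33, NF-kB and MAPK feedback list with no filter, without wild type replicate 2 and without knockout replicate 1, the immediate early list without knockout replicate 2, and the lung epithelium list with fry. With the replicate number as a block, 0 genes and 0 lists passed, and 132 genes had an unadjusted p below 0.01. The numbers pair only 2 arrays of each genotype, whose deviations from the group means correlated across genes at -0.046 and 0.143. The deviations of the 2 knockout arrays are exact opposites, so these values cannot show whether the numbers pair the samples. The main test did not take them as pairs. No neighbour of Il33 passed within 5, 10 or 20 Mb. Of the named genes and list members, 8 values reversed: Rgs2 to -0.041 and Ighm to 0.064 with the mean over probe sets, Olfr782 to 0.018 without wild type replicate 2, the array in which it was high, in a range of -3.21 to 0.018, Kdm5c to -0.0061 without wild type replicate 1, in a range of -0.0061 to 0.087, Ddx3x to 0.0017 with the replicate block and without wild type replicate 3 and to 0.14 without knockout replicate 2, in a range of -0.57 to 0.14, and Gp9 to 0.085 without knockout replicate 1, in a range of -0.345 to 0.085 when 1 array was left out. Apart from Olfr782, the cause was not tested. In 1987 other values for single genes the direction and the side of the threshold were the same, and 16 passed the threshold, all without a knockout array. Signals near the floor limit what dim genes such as Il33 can show.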

Other observations

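All tests in this part were chosen after the results they bear on had been seen. Some receptor genes of sensory neurons, which lymphocytes are not known to need, had a lower mean in knockout than in wild type. Of 441 olfactory and vomeronasal receptor genes tested, which made up 2.7% of the genes tested, 79 had a log2 difference of at least 1 downward. Genes of all kinds with such a difference numbered 235. How many receptor genes lay at least 1 upward was not determined. A single high array can make such a difference: Olfr782 lay 5.67 above the next array in wild type replicate 2 and differed by 0.018 without it. Knockout replicate 2 had such a gene too, Olfr635, 4.33 above the next array. The mean over 1394 measured receptor genes was 3.23, 3.35 and 3.04 on the wild-type arrays and 2.88 and 3.11 on the knockout arrays, so the groups overlapped. In knockout replicate 2, Gzma, a granzyme gene of cytotoxic cells, read 6.56 against 3.27 to 4.01 on the other arrays, and in knockout replicate 1 the airway gene Cbr2 read 6.86 against 4.20 to 4.62.

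The genotype split gave 355 genes at an unadjusted p below 0.01, and the highest of the other splits of the 5 arrays gave 136. Only 1 of the 10 splits gave as many, the real one, and 10 splits are too few for a share under 0.05. A labelling or hybridisation difference between the arrays of the 2 genotypes was weighed through the receptor genes of sensory neurons: they were more frequent among genes lower at that p, with an odds ratio of 5.55 (95% interval 2.97 to 9.70, Fisher's exact test), 15 of 117 genes. Among genes higher at that p they were 2 of 238, an odds ratio of 0.31 (95% interval 0.037 to 1.13). Only 441 of 1394 measured receptor genes passed the filter on the mean of all 5 arrays. Wild-type arrays are the majority there, so among dim genes the filter can favour those higher in wild type. Since the test of lower genes was also found from these values and covers 12.8% of them, such a difference and an effect of the genotype cannot be told apart.

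Xist was high in knockout replicate 2 alone, 4.81 above the next array. Among the 16635 genes tested this was the widest such gap of that array, and Xist was on the list of sex check genes fixed beforehand. On other arrays there were larger gaps, 5.67 for Olfr782 in wild type replicate 2 and 5.30 for Bpifa1 in knockout replicate 1. A spike of a single probe set unrelated to sex stays open. Of 3 Y-linked genes, 2, Eif2s3y and Kdm5d, had their lowest value in that array, which chance gives with a binomial probability of 0.104. That count over 3 genes ignores how far each lay below the other arrays, so it cannot decide. RNA of female mice only in that array would need all 3 to be low and near the floor, where the Y-linked Usp9y and Zfy2 read 2.63 and 3.25, but 2 of the 3 were low, Eif2s3y still read 6.14 and Uty was not lower. A mix of RNA of female and male mice stays open too, since Eif2s3y lay -1.0 from the mean of the other 4 arrays, while the X-linked Kdm6a read 8.06 (above the others), Kdm5c 6.44 (within the others) and Ddx3x 7.31 (below them). No female array was analysed here to give the background of these probe sets, so the hypotheses cannot be told apart.

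Trpd52l3, beside Il33, was high in both knockout arrays, with a difference of 3.31. The median difference was 0.05 over the 99 genes tested within 10 Mb and 0.0385 over all genes tested. Trpd52l3 ranked 12 of 16635 genes by the size of its difference in either direction, and 2 upward. The probability that genes with so large a difference include any gene within 10 Mb is 0.0691 in either direction and 0.0119 upward alone. Both forms count every gene within 10 Mb alike and do not use that Trpd52l3 is the measured gene next to Il33. The form in either direction was chosen after the values were seen and the 2 forms fall on opposite sides of 0.05, so a spike of a single probe set unrelated to the Il33 locus is neither argued against nor borne out. The hypothesis that the knockout allele itself changes transcription past Il33 cannot be told apart from it. The Il33 probe set was 0.51 higher in knockout, but its signal was near the floor in both genotypes, so the size of that difference is uncertain. The position of its probes relative to the allele was also not given in the sources used here.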
